A study of Mus musculus with 4 samples.

How the data were processed

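Liver RNA of 2 stress pools and 2 control pools was measured on Affymetrix arrays, 1 pool per array, each pool made from equal RNA amounts of 8 or 9 mice. Per the labels' protocols, pooled total RNA was labelled by the manufacturer's one-cycle procedure after RNA quality had been checked on a Bioanalyzer. The deposited values are linear signal intensities per probe set that the authors produced with GCOS 1.4, per the submitters' processing notes. The algorithm, the detection calls and the scaling target are not given in the sources used here. In the values themselves, all of which were positive, the 2% trimmed mean was 500.2 or 500.3 on every array, so each array had been scaled to a common level near 500. Scanner files and detection calls were not used here, so no background level per probe set was at hand.

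Signals were used with no further normalization between arrays. They were transformed as log2(signal + 21.01), where 21.01 is the 25th percentile of all values, and folds are ratios on that scale, which for dim probe sets depend on the value added. The 64 Affymetrix control probe sets were left out, as were probe sets whose mean log2 value over all 4 arrays was under the 40th percentile, which corresponds to a signal of about 51.4. This kept 13576 probe sets and removed 9050. Gene names came from the platform annotation, in which 20393 probe sets had a single symbol, 691 several and 1606 none. Of the single-symbol probe sets, 20364 matched a RefSeq gene table (assembly GRCm38.p6, used for names only) and 0 symbols needed updating. No gene was named from a probe set with several symbols or none, and this left 38 of the called probe sets unnamed. A gene was represented by its kept probe set with the highest mean, which gave 7935 genes. G6pc stands for the gene now called G6pc1.

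Stress was compared with control in limma 3.58.1 under R 4.3.3, with lmFit and eBayes with a mean-variance trend on the log2 values, two-sided, with group as the only term. The adjusted p is the Benjamini-Hochberg value over the 13576 probe sets, with a threshold of 0.05. The error given after ± beside a log2 fold change is limma's moderated standard error, on 8.61 degrees of freedom, of which 6.61 came from other probe sets. As a count that needs no variance, probe sets were counted for which each stress array was at least 1.5-fold above or below each control array, beside the same count for the other ways of dividing the arrays into pairs. In total 35 gene lists were used, covering hormonal, metabolic, stress, immune, clock and housekeeping pathways and markers of liver cell types. The 32 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over these lists. Camera compares a list with all other genes, whose median log2 fold change was -0.06, so a list with a median near 0 can pass upward. The median over probe sets was -0.05. Camera with an estimated correlation was run beside it, as was fry, which tests whether the genes of a list move one way against no change and makes no comparison with other genes. Unlike the preset version, camera with an estimated correlation is limited to the few residual degrees of freedom of the 4 arrays. Its larger p values need therefore not stem from correlation between genes.

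Each replicate is a pool from a separate experiment, so the spread between replicates is that between experiments and pools, not between single mice. The series describes 2 experiments, each with a stress and a control group, and the replicate numbers were taken to be the experiments. Deviations from the group means of pools with the same number correlated at r = 0.216 across probe sets. No source states a paired test, so the fit without the experiment as a block was the primary one.

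The named genes were taken from the 15 largest rises and the 15 largest falls past the threshold with non-overlapping arrays, up to 4 members of each list with the smallest p, and a fixed set of stress and liver genes (among them Fkbp5, Per1, Tsc22d3, Sgk1, Tat, Pck1, G6pc, Igfbp1, Mt1, Mt2, Saa1, Saa2, Lcn2, Fos, Cyp7a1 and Alb). Where a count in a list was 5 or fewer, members outside that rule were named too. The design, the lists, the naming rule and the alternatives were fixed before the data were examined. The alternatives were quantile normalization, centring on array medians, pseudocounts of 0 and of the 50th percentile (103.1), no filter and a filter at the 60th percentile, eBayes without a trend and robust eBayes, the experiment as a block, averaging all probe sets of a gene, other thresholds and leaving out each array in turn.

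The procedure was tested on simulated data with the same 13576 probe sets and 2 against 2 arrays. It recovered 14 of 67 probe sets changed 1.5-fold, 38 of 67 changed 2-fold and 65 of 66 changed 4-fold, with 10 false calls among 127 (7.87%), and made 0 calls when nothing was changed. A simulated list shifted by 0.4 on the log2 scale was called and 0 of the unchanged lists were. Errors were drawn independently for each probe set and array, with no correlation between genes and no effect of the experiment. The simulation therefore does not show how often lists of correlated genes are called falsely in the real data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.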

Results

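Liver RNA from female BALB/c mice aged 10 to 12 weeks was measured on 4 Affymetrix expression arrays, each with 22690 probe sets. Mice of the stress group spent 2 h restrained in tubes while exposed to bursts of ultrasound, and their livers were taken directly afterwards (0 h). Control mice were left untreated and housed away from them. Each array held pooled RNA of 8 or 9 mice, and each group had 2 pools, 1 from each of 2 experiments. The number of arrays limits the precision of all values. Every array had a trimmed mean signal of 500.2 or 500.3, in arbitrary intensity units, and a median signal between 99.47 and 108.2. Across probe sets on the log2 scale, the stress pools correlated with each other at r = 0.989, the control pools at 0.987, and pools of different groups at 0.975 to 0.978; probe sets are not independent replicates. The ratio of 3' to 5' signal, a sign of RNA integrity, was 0.69 to 0.697 for Gapdh and 1.7 to 1.83 for actin over the 4 arrays. Both ratios were slightly higher on the stress arrays (actin 1.83 and 1.79, Gapdh 0.697 and 0.695) than on the control arrays (1.7 and 1.75, 0.694 and 0.69).

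The comparison of stress with control pools asked which liver transcripts differ at the end of a single stress session. Many of the largest rises were of genes known to be induced by glucocorticoids. Cdkn1a, an inhibitor of cell cycle kinases, went from a signal of 89.35 ± 8.86 in controls to 2758 ± 219.9 after stress (SD, n = 2 pools per group). On the scale of the test, where 21.01 was added to every signal, that was a 25.2-fold rise, or a log2 fold change of 4.65 ± 0.14 (limma's standard error, adjusted p = 2.71e-06). The log2 value was 4.95 with nothing added and 3.89 with the median signal added, and all other folds are also on the scale of the test. Lpin1, a phosphatidate phosphatase and coactivator of fat oxidation genes, rose 12.5-fold (3.64 ± 0.14, adjusted p = 8.18e-06), and Fkbp5, a co-chaperone of the glucocorticoid receptor, rose 5.57-fold (2.48 ± 0.15, adjusted p = 4.91e-05). Pck1 and G6pc, which encode the first committed and the last enzyme of gluconeogenesis, both rose 2.16-fold. Among the falls were Osgin1, a regulator of growth under oxidative stress, by 6.63-fold (log2 fold change -2.73 ± 0.20, adjusted p = 0.000138), and Angptl8, a feeding-induced hormone of triglyceride handling, by 3.83-fold (-1.94 ± 0.24, adjusted p = 0.00261). Alb, which encodes albumin, had a log2 fold change of -0.01 ± 0.10 (adjusted p = 0.989), with a sign that changed when arrays were centred on their medians (0.06) and without stress pool 1 (0.12) or control pool 2 (0.01).

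**Figure D1:**
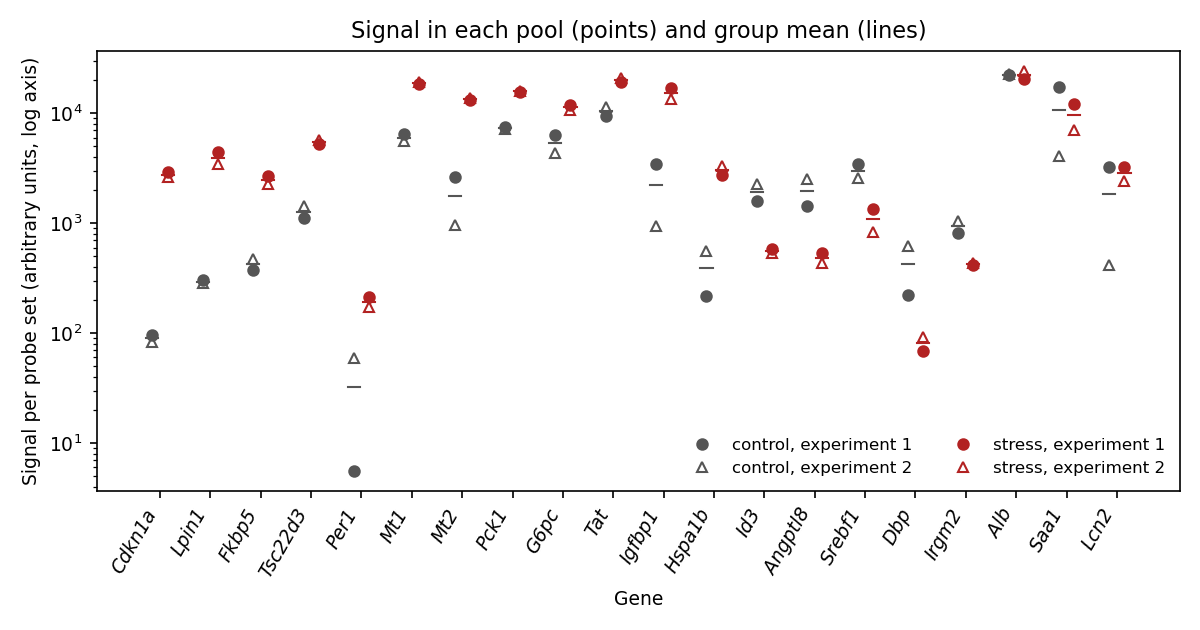
Signal of 20 named genes (log axis, arbitrary intensity units) in each of the 4 pools, with control pools in grey, stress pools in red, circles for experiment 1, triangles for experiment 2 and lines for group means. Stress signals of Cdkn1a lie at 2603 and 2914 against 83.08 and 95.61 in controls, while those of Saa1 and Lcn2 lie within the range of the control pools.

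Of the 13576 probe sets tested with limma, 437 passed an adjusted p of 0.05, of which 293 were higher and 144 lower after stress (67% higher). Over all probe sets tested, 37.9% were higher. In all 437, both stress arrays lay on the same side of both control arrays, which selection on the same arrays favours. At least 1.5-fold changes made up 409 of them (279 higher and 130 lower), at least 2-fold changes 223 (169 and 54) and at least 4-fold changes 49 (44 and 5). Counted by gene, 263 of 7935 changed, 167 upward and 96 downward. Of the 80 genes with at least 2 called probe sets, 0 were called in both directions. Stress and control arrays did not overlap for 5809 probe sets (42.8%), where chance gives 33.3%, and the other 2 ways of splitting the arrays gave 36.2% (experiment 1 against experiment 2) and 21%. A probe set can be apart in only 1 of these splits, so the shares depend on each other. For 373 probe sets every stress array lay at least 1.5-fold from every control array (248 above and 125 below). The same count was 47 for experiment 1 against experiment 2 and 6 for the remaining way of splitting the arrays. Both of those splits gave 0 probe sets past limma's adjusted threshold, with 765 and 125 at an unadjusted p under 0.05, against 1790 (705 higher and 1085 lower) for stress against control. In those fits the difference between stress and control counted as residual spread, which works against calls. Their counts therefore do not estimate the false calls of the real comparison. Fold changes of the 2 experiments correlated across probe sets at r = 0.567, and at 0.945 over the 437 called on the same arrays. With 2 arrays per group, an exact two-sided permutation test of a single gene cannot give a p below 1 in 3, so each call rests on a variance that limma shares across probe sets. The count of 437 became 676 without control pool 1, 681 without control pool 2, 224 with no filter on dim probe sets and 228 with no mean-variance trend. The count of 373 became 657 without stress pool 1 (319 above and 338 below), 667 without stress pool 2 (332 and 335), 653 without control pool 1 (362 and 291) and 701 without control pool 2 (406 and 295), so its upward majority was lost without either stress pool.

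**Figure D2:**
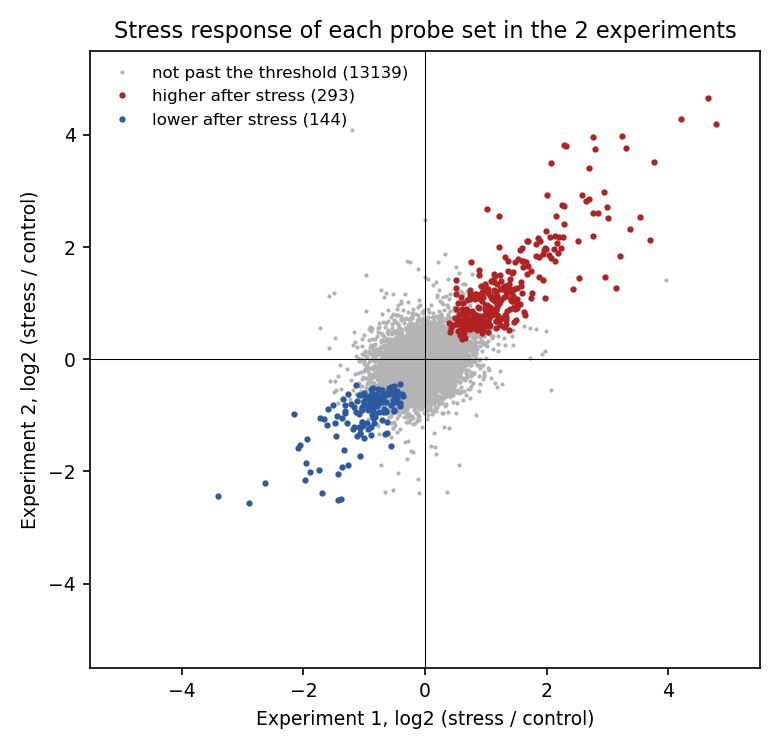
Log2 fold change of stress over control in experiment 1 (horizontal axis) and in experiment 2 (vertical axis) for the 13576 probe sets tested, with probe sets past the threshold in red (293 higher) or blue (144 lower) and the others in grey. All called probe sets lie in the lower left or upper right quadrant, which their selection on the same arrays favours, and over all probe sets r was 0.567.

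Of 35 measured genes in the list of glucocorticoid-responsive genes, 27 rose, 0 fell and 8 did not pass the test over all genes. Adjusted over the list alone, 28 rose and 1 was lower. The list shifted upward against other genes (camera, adjusted p = 8.79e-52), with adjusted p = 0.155 with an estimated correlation. Fry, which tests a list against no change and not against other genes, gave an adjusted p of 0.0159. Besides Cdkn1a, Lpin1 and Fkbp5, members that rose included St3gal5, a ganglioside-forming sialyltransferase (2.85 ± 0.11, 7.21-fold, adjusted p = 8.43e-06), and Gadd45g, a stress sensor related to growth arrest (3.54 ± 0.20, 11.6-fold). Tsc22d3, which encodes the anti-inflammatory protein GILZ, rose 4.3-fold (2.10 ± 0.14, adjusted p = 8.43e-05), the metallothioneins Mt1 and Mt2 rose by 1.66 ± 0.10 and 3.06 ± 0.35 on the log2 scale, and the clock gene Per1 rose by 2.21 ± 0.44 (adjusted p = 0.031). Sgk1, a kinase that regulates sodium transport, rose by 0.74 ± 0.14 (adjusted p = 0.022). The call of Sgk1 was lost without stress pool 2 (0.58, adjusted p = 0.106). With all probe sets of a gene averaged, the log2 value of Mt1 was 2.63 and that of Tsc22d3 1.53. Control pools differed widely for some of these genes, so the log2 fold change of Mt2 was 3.77 without control pool 1 and 2.35 without control pool 2, that of Per1 1.41 and 3.0, and that of Igfbp1, an insulin-repressed binding protein of growth factors (3.05 ± 0.47), 3.99 and 2.12. The calls of Mt2 (adjusted p = 0.263), Igfbp1 (0.413) and Per1 (0.112) were lost with robust variance moderation, and that of Per1 also with a pseudocount of 0 (0.0974). Per1 was dim, and its log2 fold change ran from 1.15 to 3.40 over the pseudocounts tried.

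Of 25 measured members of the gluconeogenesis and glycogen list, 9 rose, 0 fell and 16 did not pass, with 9 and 0 adjusted over the list alone. The list shifted upward (camera, adjusted p = 2.33e-10), with adjusted p = 0.275 with an estimated correlation, while fry, tested against no change, gave 0.0159. Its mean was 0.51 and its median 0.16. Pck1 rose by 1.11 ± 0.08 (adjusted p = 0.000189), from a signal of 7312 ± 215.7 to 15820 ± 134.2. G6pc, glucose-6-phosphatase, rose by 1.11 ± 0.16 (adjusted p = 0.0058), and Slc37a4, the transporter that feeds it, by 0.86 ± 0.10 (adjusted p = 0.00245). The call of G6pc was lost with no filter on dim probe sets (adjusted p = 0.0526) and with no mean-variance trend (0.0663). The transcriptional regulators Foxo1 and Ppargc1a rose by 1.27 ± 0.13 and 1.32 ± 0.17 (adjusted p = 0.000999 and 0.00425). A second, dim Pck1 probe set had a log2 fold change of -0.26 ± 0.26 (adjusted p = 0.784), and the call of Pck1 was lost when its probe sets were averaged (0.43, adjusted p = 0.161). In the amino acid catabolism and urea cycle list, 3 of 31 measured genes rose, 0 fell and 28 did not pass, with 4 higher and 1 lower adjusted over the list alone. The transaminases Tat (0.95 ± 0.10, adjusted p = 0.00127), Gpt2 (0.71 ± 0.10, adjusted p = 0.00462) and Got1 (0.63 ± 0.09, adjusted p = 0.0063) were the ones that rose. The list passed camera upward (adjusted p = 0.00508), with adjusted p = 0.534 with an estimated correlation, 0.151 after quantile normalization and 0.113 without stress pool 2.

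Of 30 measured genes in the list of fatty acid oxidation, ketogenesis and PPAR alpha targets, 7 rose, 1 fell and 22 did not pass, with 8 and 2 adjusted over the list alone. The list passed camera upward (adjusted p = 2.32e-05), with adjusted p = 0.534 with an estimated correlation, while fry, tested against no change, gave 0.38. Its mean was 0.30 but its median 0.05, so the shift came from some of its members. The mean was 0.42 without control pool 1 and 0.19 without control pool 2. Angptl4, an inhibitor of lipoprotein lipase, rose 5.51-fold (2.46 ± 0.28, adjusted p = 0.00176), although not past the threshold with robust variance moderation (adjusted p = 0.112). Acot1, an acyl-CoA thioesterase, rose by 1.76 ± 0.14 (adjusted p = 0.00029) and Pex11a, a factor of peroxisome division, by 1.10 ± 0.10 (adjusted p = 0.000525). Acot3, a related thioesterase, fell by 1.04 ± 0.14 on the log2 scale (adjusted p = 0.004), on a probe set that can detect several similar transcripts. Angptl4, Mt1, Dbp, Cyp2b10, Fmo5, Foxo1, Gpt2 and Hnf4a, among others, were measured on probe sets of the same type. The lipid droplet proteins Plin4 and Plin5 rose 9.64-fold and 5.11-fold (3.27 ± 0.27 and 2.35 ± 0.14, adjusted p = 0.000298 and 4.65e-05). Control signals of Plin4 were 45.69 and 16.24, and its log2 value ran from 2.08 to 4.08 over the pseudocounts tried. Plin2, another lipid droplet protein, named after its value was seen, had 0.27 ± 0.12 (adjusted p = 0.362), with 0.44 without control pool 1 and 0.11 without control pool 2. In the fatty acid and triglyceride synthesis list, 3 of 23 measured genes rose, 1 fell and 19 did not pass, with 3 and 2 adjusted over the list alone, and the list as a whole did not pass camera (adjusted p = 0.374; mean 0.12, median -0.08). The risers were Lpin1, its relative Lpin2 (1.63 ± 0.11, adjusted p = 8.97e-05) and the lipogenic factor Thrsp (0.80 ± 0.12, adjusted p = 0.00653). Srebf1, a master regulator of lipogenic genes, was the member that fell (-1.48 ± 0.22, adjusted p = 0.00769). Of 19 measured genes of cholesterol synthesis and uptake, 0 rose, 2 fell and 17 did not pass, with 0 and 4 adjusted over the list alone (camera downward, adjusted p = 0.0998). Fdft1, squalene synthase, fell by 0.58 ± 0.10 (adjusted p = 0.0198), and Mvd, a decarboxylase of the mevalonate route, fell by 0.82 ± 0.16 (adjusted p = 0.0337). Mvd missed the threshold without stress pool 1 (-0.80, adjusted p = 0.0743), stress pool 2 (-0.84, 0.0748) or control pool 2 (-0.67, 0.0732). Of 21 measured genes of bile acid synthesis and transport, 0 passed in either direction, also adjusted over the list alone (camera, adjusted p = 0.257; median 0.01, mean -0.02). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had signals of 1050 and 717.9 after stress and of 1121 and 3831 in controls (-1.24 ± 0.45, adjusted p = 0.271). Its value was -1.51 without stress pool 1, -2.11 without control pool 1 and -0.36 without control pool 2.

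Of 22 measured heat shock proteins and chaperones, 4 rose, 0 fell and 18 did not pass over all genes, while 10 were higher and 0 lower adjusted over the list alone. The list shifted upward (camera, adjusted p = 7.58e-10; mean 0.58, against 0.38 without control pool 1 and 0.77 without control pool 2), with adjusted p = 0.531 with an estimated correlation. Hspa1b, an inducible HSP70 chaperone, rose 8.16-fold (3.03 ± 0.33, adjusted p = 0.00146), with 2.39 without control pool 1 and 3.67 without control pool 2, and missed the threshold with robust variance moderation (adjusted p = 0.137). Its near-identical copy Hspa1a rose by 1.68 ± 0.23 (adjusted p = 0.00462; 0.80 with a pseudocount at the 50th percentile), and the probe sets of these genes may share targets. The co-chaperones Hspb8 and Dnajb1 rose by 0.67 ± 0.10 and 0.96 ± 0.19 (adjusted p = 0.00676 and 0.0287), the latter at an adjusted p of 0.0517 when its probe sets were averaged. Of 29 measured genes of endoplasmic reticulum stress and ATF4 targets, 5 rose, 1 fell and 23 did not pass, also adjusted over the list alone (camera upward, adjusted p = 0.000742). That list had a mean of 0.34 but a median of 0.01, with adjusted p = 0.531 with an estimated correlation and 0.237 by fry. Herpud1, a component of protein degradation at the endoplasmic reticulum, rose by 2.05 ± 0.10 (adjusted p = 2.49e-05). Cebpb, a transcription factor of the acute phase and of glucose production, rose by 2.35 ± 0.20 (adjusted p = 0.000311), the mTOR inhibitor Ddit4 by 2.72 ± 0.16 (adjusted p = 4.65e-05), and the glutathione-degrading enzyme Chac1 by 1.27 ± 0.22 (adjusted p = 0.016). The hormone gene Fgf21 (1.23 ± 0.23, adjusted p = 0.0226) and the lipoprotein receptor gene Vldlr (-0.68 ± 0.15, adjusted p = 0.0442), named after their values were seen, completed that count. Fgf21 was not called without stress pool 1 (0.90, adjusted p = 0.0657), nor Vldlr without stress pool 1 (-0.69, 0.0697), stress pool 2 (-0.68, 0.0922) or control pool 1 (-0.50, 0.0819), with arrays centred on their medians (-0.62, 0.067), after quantile normalization (-0.66, 0.0716) or with its probe sets averaged (-0.67, 0.0769).

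Of 24 measured immediate early genes, 9 rose, 1 fell and 14 did not pass, with 9 and 2 adjusted over the list alone. Camera placed the list upward (adjusted p = 0.000742; mean 0.34, median 0.02, with a mean of 0.61 without control pool 1), with adjusted p = 0.531 with an estimated correlation. Dusp1, a phosphatase that switches off MAP kinases, rose 4.01-fold (2.00 ± 0.12, adjusted p = 4.65e-05), the matrix protein gene Ccn2 4.57-fold (2.19 ± 0.18, adjusted p = 0.000274) and the antiproliferative gene Btg2 2.22-fold (1.15 ± 0.14, adjusted p = 0.00289). The log2 value of Ccn2 ran from 1.48 to 2.53 over the pseudocounts tried. Fos, a subunit of AP-1, rose by 1.25 ± 0.27 (adjusted p = 0.0434), and lost the call without stress pool 2 (1.19, adjusted p = 0.0577) or with a pseudocount of 0 (adjusted p = 0.0529), while its value was 0.82 without control pool 2. Of 33 measured genes of apoptosis and p53 targets, 8 rose, 1 fell and 24 did not pass, with 9 and 3 adjusted over the list alone. This list passed camera upward (adjusted p = 0.00623; mean 0.33), although its median was -0.02, and had adjusted p = 0.531 with an estimated correlation. Its risers included Cdkn1a, Gadd45g, Gadd45b (2.12 ± 0.17, adjusted p = 0.000274) and Trp53inp1, a p53-inducible autophagy factor (1.97 ± 0.10, adjusted p = 3.02e-05). Gadd45a, of the same family as Gadd45b and Gadd45g, fell by 2.04 ± 0.24 on the log2 scale (adjusted p = 0.00218), the member that fell in both lists. Its stress signals were 27.17 and 15.14, and its value ran from -2.89 to -1.03 over the pseudocounts tried. Of 20 measured genes of the hypoxia response, 3 rose, 0 fell and 17 did not pass, with 4 and 0 adjusted over the list alone. They were Ddit4, the glycolytic regulator Pfkfb3 (1.99 ± 0.27, adjusted p = 0.00453) and the mitophagy gene Bnip3 (0.59 ± 0.10, adjusted p = 0.0119), which missed the threshold without stress pool 2 (0.52, adjusted p = 0.0602). The value of Pfkfb3 ran from 1.16 to 2.51 over the pseudocounts tried. The hypoxia list passed camera upward (adjusted p = 0.0173; mean 0.24, median -0.03), with adjusted p = 0.531 with an estimated correlation, 0.159 with a filter at the 60th percentile and 0.0501 without stress pool 1. Of 28 measured genes of oxidative stress and NRF2 targets, 2 rose, 0 fell and 26 did not pass, also adjusted over the list alone. These were the metal-binding Mt1 and Mt2, and the list did not pass (camera, adjusted p = 0.796; mean 0.09, median -0.05). Of 16 measured cell cycle genes, Cdkn1a rose, 0 fell and 15 did not pass, with 1 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.25, downward; median -0.20, mean 0.00).

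Inflammatory genes moved in different directions. Of 28 measured acute phase genes, 4 rose, 0 fell and 24 did not pass, with 6 and 0 adjusted over the list alone. The list shifted upward (camera, adjusted p = 1.41e-06), with a mean of 0.34 and a median of 0.11. Its adjusted p was 0.531 with an estimated correlation and 0.237 by fry. The size of this shift depended on the control pools, with a mean of 0.59 without control pool 1 and of 0.09 without control pool 2. Besides Mt1 and Mt2, these were the constitutive serum amyloid gene Saa4 (1.11 ± 0.09, adjusted p = 0.000327) and the metalloreductase gene Steap4 (0.76 ± 0.16, adjusted p = 0.0368), which lost the call without stress pool 1 (0.67, adjusted p = 0.0579). The inducible acute phase genes Saa1, Saa2 and Lcn2 did not pass, at 0.14 ± 0.54, -0.59 ± 0.95 and 1.24 ± 0.72 (adjusted p = 0.959, 0.88 and 0.544). Their control pools stood far apart, with signals of 17250 and 4076 for Saa1, 10490 and 803.1 for Saa2, and 3262 and 416.2 for Lcn2 in control pools 1 and 2. Without control pool 1 the log2 fold changes were 1.18, 1.25 and 2.69, and without control pool 2 they were -0.90, -2.42 and -0.22. The sign of Saa1 also turned without stress pool 1 (-0.24), and that of Saa2 without stress pool 2 (0.11). Of 19 measured NF-kB and inflammatory cytokine targets, 5 rose, 2 fell and 12 did not pass, also adjusted over the list alone. They were the cytokine receptor genes Il6ra (2.31 ± 0.17, 4.96-fold, adjusted p = 0.000145) and Il1r1 (1.90 ± 0.17, adjusted p = 0.000406), the adhesion molecule gene Vcam1 (1.69 ± 0.16, adjusted p = 0.000512), the chemokine gene Cxcl1 (1.85 ± 0.17, adjusted p = 0.000548) and the NF-kB inhibitor gene Nfkbia (0.77 ± 0.10, adjusted p = 0.00301), the last named after its value was seen. Tnfaip2 and Irf1 fell (-1.68 ± 0.18 and -0.72 ± 0.13, adjusted p = 0.00118 and 0.0185), Irf1 with -0.66 without stress pool 1 (adjusted p = 0.0761). The NF-kB list passed camera upward (adjusted p = 0.00623), while fry gave an adjusted p of 0.186. Its mean was 0.30, against 0.14 without stress pool 2, and its median 0.07. It had adjusted p = 0.531 with an estimated correlation, 0.0905 with no filter on dim probe sets and 0.0578 with probe sets averaged per gene.

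Of 30 measured genes of the interferon response, 0 rose, 4 fell and 26 did not pass, with 0 and 5 adjusted over the list alone. Of the 30, 28 had a value below 0, against 5024 of all 7935 genes. The list shifted downward (camera, adjusted p = 0.000596), with adjusted p = 0.533 with an estimated correlation. The genes that fell were Irgm2 (-1.09 ± 0.15, adjusted p = 0.00541), Igtp (-0.60 ± 0.11, adjusted p = 0.0204) and Irgm1 (-0.63 ± 0.13, adjusted p = 0.0394), which encode immunity-related GTPases, and the transcription factor gene Irf1. Without stress pool 1, Irf1 was at -0.66 (adjusted p = 0.0761), Igtp at -0.57 (0.0802) and Irgm1 at -0.62 (0.0827). Without stress pool 2, Igtp was at -0.63 (adjusted p = 0.0547) and Irgm1 at -0.64 (0.0894), and without control pool 2 Irgm1 was at -0.49 (0.0733). Irgm1 also missed the threshold after quantile normalization (adjusted p = 0.0538) and with arrays centred on their medians (0.0534). Of 20 measured genes of antigen presentation by MHC, 0 passed in either direction, also adjusted over the list alone (camera downward, adjusted p = 0.159). The same held for 40 measured genes of complement and coagulation (camera, adjusted p = 0.195).

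Clock genes changed in both directions. Of 19 measured genes of the circadian clock and its output, 4 rose, 2 fell and 13 did not pass, with 7 and 5 adjusted over the list alone (camera, adjusted p = 0.123; mean 0.25, median -0.12). Per1 rose, as did Alas1, the rate-limiting enzyme of haem synthesis (2.21 ± 0.32, adjusted p = 0.00639), the repressor gene Nfil3 (0.93 ± 0.14, adjusted p = 0.00743) and, named after its value was seen, the deubiquitinase gene Usp2 (1.61 ± 0.32, adjusted p = 0.0323). Dbp, a clock-driven transcription factor, fell by 1.97 ± 0.38 on the log2 scale (adjusted p = 0.029), as did the kinase gene Wee1 (-1.01 ± 0.21, adjusted p = 0.0403), also named after its value was seen. The value of Per1 was 1.41 without control pool 1 and 3.0 without control pool 2, that of Alas1 1.59 and 2.83, and that of Dbp -2.67 and -1.27. With robust variance moderation, Per1, Alas1 and Dbp missed the threshold (adjusted p = 0.112, 0.308 and 0.169). Usp2 was not called without stress pool 2 (1.07, adjusted p = 0.051), nor Wee1 without stress pool 1 (-0.91, 0.114) or control pool 1 (-0.95, 0.0759), after quantile normalization (-0.94, 0.0601) or with arrays centred on their medians (-0.95, 0.0547). Over the pseudocounts tried, Per1 ran from 1.15 to 3.40, Usp2 from 1.04 to 1.89 and Wee1 from -1.33 to -0.53. Of 25 measured genes of the growth hormone and IGF axis and STAT5 targets, 4 rose, 1 fell and 20 did not pass, with 5 and 3 adjusted over the list alone (camera, adjusted p = 0.41; mean 0.15, median -0.08). Igfbp1 and Acot1 rose, as did the transcriptional repressor gene Bcl6 (1.84 ± 0.25, adjusted p = 0.00496) and, named after its value was seen, the binding protein gene Igfbp3 (0.91 ± 0.17, adjusted p = 0.0207). Cish, a STAT5-induced inhibitor of cytokine signalling, fell by 1.11 ± 0.18 (adjusted p = 0.0119). Igfbp3 was not called without stress pool 1 (0.88, adjusted p = 0.0619) or stress pool 2 (0.93, 0.0577), and the log2 fold change of Igfbp1 was 3.99 without control pool 1 and 2.12 without control pool 2. Of 36 measured genes of cytochrome P450 and xenobiotic metabolism, 3 rose, 0 fell and 33 did not pass, with 4 and 0 adjusted over the list alone (camera, adjusted p = 0.25; mean 0.07, median -0.05). Besides Alas1 these were the monooxygenase genes Fmo5 (0.88 ± 0.11, adjusted p = 0.00346) and Cyp2b10 (0.52 ± 0.10, adjusted p = 0.0306), the latter at 0.43 without stress pool 2 (adjusted p = 0.166).

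Housekeeping groups had no called members. Of 49 measured genes of oxidative phosphorylation, 0 passed in either direction, also adjusted over the list alone (camera, adjusted p = 0.159; mean 0.01). Of 31 measured genes of the proteasome and of ubiquitin ligases of atrophy, 0 passed, also adjusted over the list alone (camera upward, adjusted p = 0.481; mean -0.01, median -0.01). Of 39 measured cytosolic ribosomal protein genes, 0 passed, also adjusted over the list alone, while 34 had values above 0. With a mean of 0.04, that list passed camera upward (adjusted p = 0.0073) against a median of -0.06 over all genes. It had adjusted p = 0.534 with an estimated correlation, 0.35 after quantile normalization, 0.0817 without stress pool 2 and 0.215 without control pool 2.

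Markers of the cells a piece of liver holds were also compared. Of 14 measured hepatocyte markers, Tat and the nuclear receptor gene Hnf4a (0.54 ± 0.09, adjusted p = 0.0158) rose, 0 fell and 12 did not pass, also adjusted over the list alone. The call of Hnf4a was lost without stress pool 2 (0.53, adjusted p = 0.0557). The hepatocyte list passed camera upward (adjusted p = 0.013; mean 0.12), with adjusted p = 0.678 with an estimated correlation and 0.0574 after quantile normalization. Its mean was 0.20 without stress pool 1, 0.05 without stress pool 2, 0.06 without control pool 1 and 0.19 without control pool 2. Of 17 measured macrophage and Kupffer cell markers, 1 rose, 0 fell and 16 did not pass, also adjusted over the list alone (camera downward, adjusted p = 0.385). It was the scavenger receptor gene Cd163 (0.84 ± 0.17, adjusted p = 0.036), which was not called without stress pool 2 (0.70, adjusted p = 0.151). Beside the fall of 4 genes of the interferon list, 16 of these 17 markers had values below 0, with a median of -0.11. Over all 7935 genes, 5024 had values below 0, with a median of -0.06. Of 5 measured neutrophil and monocyte markers, 0 passed, also adjusted over the list alone (camera upward, adjusted p = 0.481; mean 0.23, median -0.06). The 6 measured B cell markers all had values below 0 (median -0.28), with 0 past the test, also adjusted over the list alone (camera, adjusted p = 0.25). Of 17 measured sinusoidal endothelial markers, 0 passed, also adjusted over the list alone (camera upward, adjusted p = 0.563; mean 0.01, median -0.04). Of 14 measured stellate cell and fibroblast markers, 0 passed over all genes and 1 was lower adjusted over the list alone (camera upward, adjusted p = 0.563; mean -0.04, median 0.04). Of 5 measured erythroid markers, 0 passed, also adjusted over the list alone (camera upward, adjusted p = 0.62; mean 0.02, median -0.04). Too few genes were measured to test the remaining lists as sets. Of 3 measured T and NK cell markers, the lymphocyte antigen gene Cd52 fell (-0.83 ± 0.17, adjusted p = 0.0394), also adjusted over the list alone, but not without stress pool 1 (-0.86, adjusted p = 0.0787), stress pool 2 (-0.79, 0.137) or control pool 1 (-0.79, 0.0686), nor with arrays centred on their medians (-0.76, 0.0553) or after quantile normalization (-0.75, 0.0604). Of 2 cholangiocyte markers and 3 markers of adipose, pancreas and muscle carry-over, 0 passed, also adjusted over the lists alone.

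**Figure D3:**
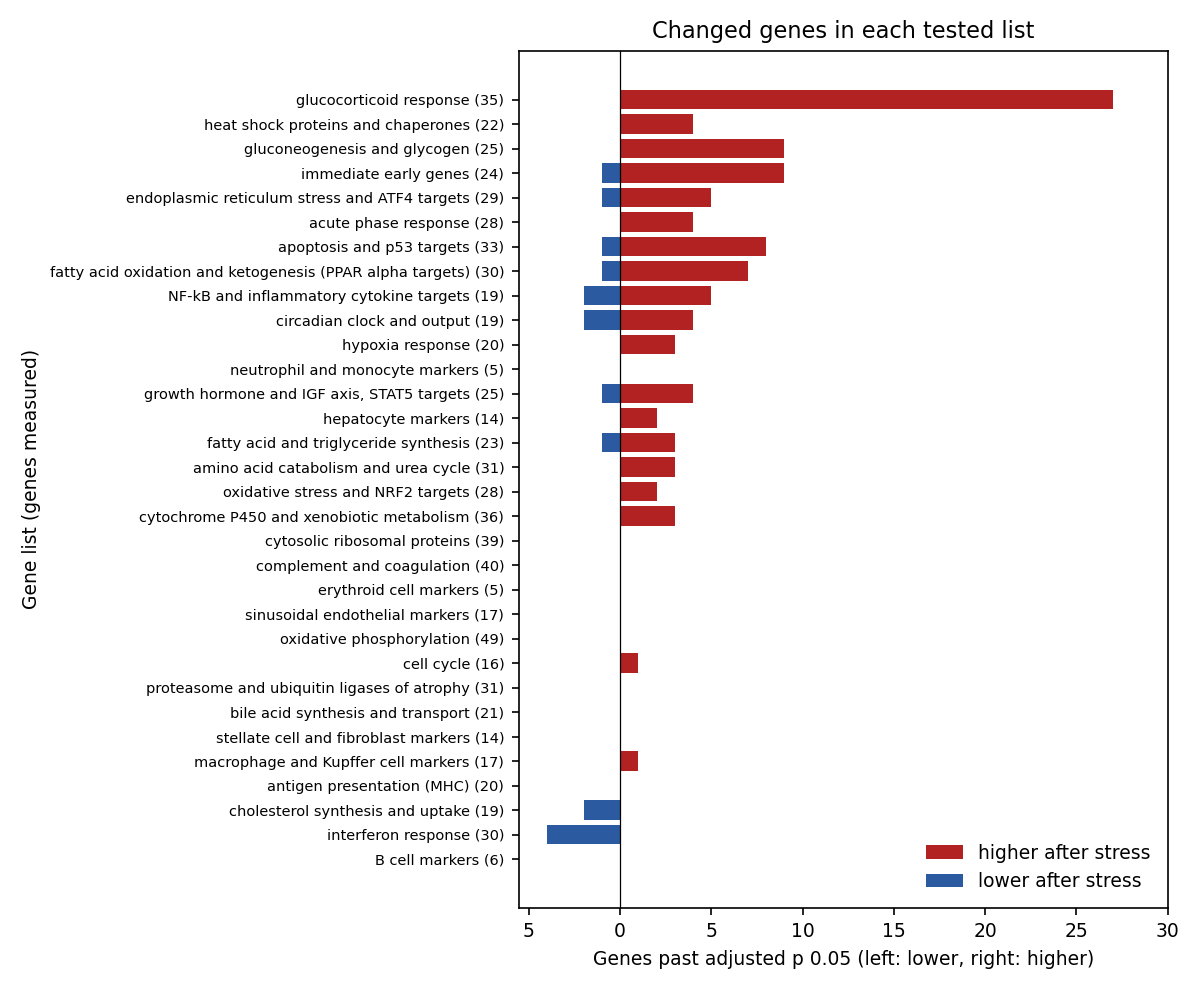
Number of genes past an adjusted p of 0.05 in each of the 32 tested lists, with genes higher after stress to the right of 0 and genes lower after stress to the left, and the number of measured genes beside each name. The glucocorticoid response list has 27 of its 35 measured genes to the right, and the interferon response list has 4 of 30 to the left.

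Together, 14 of the 32 tested lists passed camera with its preset correlation, 13 upward and 1 downward. That split was 9 and 4 without stress pool 2, 13 and 3 without control pool 1, 12 and 3 with no filter, and 10 and 2 after quantile normalization. With an estimated correlation 0 of them passed, the smallest adjusted p being 0.155 in a test with few residual degrees of freedom. That correlation was 0.017 for the glucocorticoid list, -0.032 for gluconeogenesis and -0.017 for hypoxia, near or below the preset 0.01. For these lists correlation between genes does not account for the lost call. It was higher in others, such as heat shock proteins (0.29) and hepatocyte markers (0.87). By fry, which makes no comparison with other genes, 2 lists moved one way on balance and 19 changed in either direction.

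Some of the largest changes lay mainly outside these lists. Among rises, the kinase gene Pim3 reached 2.49 ± 0.16 (adjusted p = 8.43e-05) and the uncharacterised gene 1810055G02Rik 2.51 ± 0.28 (adjusted p = 0.00168). Rgs16, an inhibitor of G protein signalling and a member of the glucocorticoid list, rose by 2.79 ± 0.38 (adjusted p = 0.00462). Rgs16 stood at 3.54 without control pool 1 and 2.04 without control pool 2, and it and 1810055G02Rik missed the threshold with robust variance moderation (adjusted p = 0.284 and 0.0584). Among falls, Pde4b, a phosphodiesterase that degrades cyclic AMP, was at -1.90 ± 0.19 (adjusted p = 0.000811), the cytidine deaminase gene Cda at -1.83 ± 0.17 (adjusted p = 0.000512), and Gas1, a hedgehog co-receptor, at -1.79 ± 0.17 (adjusted p = 0.000621). Id3, an inhibitor of helix-loop-helix transcription factors, fell 3.33-fold (-1.74 ± 0.17, adjusted p = 0.000607), and the Wnt receptor gene Fzd7 fell 3.12-fold (-1.64 ± 0.19, adjusted p = 0.00168). Tgm1, Rnf186 and Fam89a fell by 1.57 ± 0.22, 1.56 ± 0.26 and 1.42 ± 0.13 on the log2 scale (adjusted p = 0.00597, 0.0121 and 0.000512). Fen1, a flap endonuclease of DNA replication, had the most negative value (-2.92 ± 0.29, adjusted p = 0.000679) on a probe set prone to cross-hybridization. Its other probe set gave -0.56 ± 0.23 (adjusted p = 0.335), so the size of this fall is uncertain. Pim3, Fdft1 and Saa2, among others, were also measured on probe sets prone to cross-hybridization. Over the pseudocounts tried, Fen1 ran from -3.61 to -1.85 and Tgm1 from -2.01 to -0.88.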

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

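All alternatives here were fixed before the data were examined, apart from the 2-fold and 4-fold minimum on called probe sets. The count of 437 changed probe sets stayed between 385 and 608 under changes of scaling, pseudocount, filter percentile, robust moderation and block, with an adjusted p under 0.10 and with a 1.5-fold minimum, but was 223 with a 2-fold minimum, 49 with a 4-fold minimum, 224 with no filter, where 22626 probe sets were tested, and 228 with no mean-variance trend. Leaving out 1 array gave 392 to 681, with the lone array assumed to vary like those of the other group. The count of 373 probe sets apart by 1.5-fold was 575 with no filter, 151 at 2-fold, and 653 to 701 with 1 array left out, where fewer arrays have to be apart. The count of 14 called lists was 13 to 16 with 1 array left out (9 to 14 upward and 1 to 4 downward), 0 with an estimated correlation and 2 by fry. With the replicate block (the experiment as a term, paired analysis), 608 probe sets were called, including all 437, and 14 lists; it changed no call of a list and ended none of a named gene, while 7 uncalled genes under the naming rule, none of them named here, gained one. Quantile normalization kept 405 of the 437 and centring on medians 408, with 70.6% and 74.6% of all calls upward against 67%. Some signs reversed: Alb was 0.06 with arrays centred on their medians, and with 1 array left out ranged from -0.13 to 0.12, Saa1 from -0.90 to 1.18, Saa2 from -2.42 to 1.25 and Lcn2 from -0.22 to 2.69, each over control pools that stood far apart except for Alb. Otherwise the cause of these shifts was not tested. For the 123 named genes, the alternatives that used all 4 arrays gave 1210 values. Of these, 1112 kept their direction and side of the threshold, 97 lost the call, 0 gained one and 1 reversed. Losses were most frequent with no filter (35 genes) and no trend (39), against 9 with robust moderation. With 1 array left out, the spread came from the other group alone. Calls kept or lost in those fits are therefore no measure of stability. With no filter and also with no trend, the calls of G6pc, Per1, Sgk1, Igfbp1, Srebf1, Fdft1, Mvd, Dnajb1, Chac1, Fgf21, Vldlr, Fos, Bnip3, Steap4, Irf1, Irgm1, Alas1, Usp2, Dbp, Cyp2b10, Hnf4a, Cd163, Rnf186, Irs1, Cirbp, Tbx3 and Fzd8 were lost. With no filter alone, so were those of Wee1, Igfbp3, Cish, Cd52, Tgm1, Plk2, Lgr5 and Rnf43, and with no trend alone those of Gpt2, Got1, Thrsp, Hspb8, Nfkbia, Igtp, Nfil3, Fmo5, Slc25a25, Slc25a47, Cldn1 and Cldn3. Averaging the probe sets of a gene moved Mt1 from 1.66 to 2.63, Tsc22d3 from 2.10 to 1.53, Gadd45b from 2.12 to 1.57, Il6ra from 2.31 to 1.63, Klf3 from 1.29 to 0.68 and Fen1 from -2.92 to -1.74. For the called lists, 169 of 182 values kept the call and 13 lost it, in the lists of amino acid catabolism, NF-kB targets, hypoxia, ribosomal proteins and hepatocyte markers. Camera has no robust option, so that alternative was not run for lists, and some dim named probe sets, Hspa1a and Gadd45a among them, fell under the filter and have no value in some alternatives. No background level was at hand, and sizes for dim genes moved with the pseudocount, such as Per1 from 1.15 to 3.40.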

Other observations

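The genes of this and the next paragraph were chosen after their values were seen, as were the tests of p53 activation, of lower Wnt signalling and of less pericentral tissue. Klf15, a glucocorticoid-responsive regulator of amino acid use, rose 2.83-fold (limma, adjusted p = 0.000465), and its relatives Klf9, Klf3 and Klf13 rose by 1.03 ± 0.10, 1.29 ± 0.17 and 1.19 ± 0.18 on the log2 scale (adjusted p = 0.00062, 0.00371 and 0.00724), Klf3 with 0.68 when its probe sets were averaged (adjusted p = 0.0258). Cebpd rose by 1.95 ± 0.16 (adjusted p = 0.000298) and Cebpb by 2.35 ± 0.20, while Cebpa, which maintains hepatocyte identity, fell by 1.08 ± 0.10 (adjusted p = 0.000476) and the pioneer factor gene Foxa2 by 0.86 ± 0.14 (adjusted p = 0.00961). Among polo-like kinases, Plk3 rose by 2.00 ± 0.17 (adjusted p = 0.000311) and Plk2 fell by 1.14 ± 0.19 (adjusted p = 0.0123), the latter running from -1.34 to -0.73 over the pseudocounts tried. Tnfrsf1b, a receptor for tumour necrosis factor, rose by 1.68 ± 0.14 (adjusted p = 0.00029).

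The autophagy kinase gene Ulk1 rose by 1.26 ± 0.16 (adjusted p = 0.00319), the autophagy regulator gene Trp53inp2 by 1.20 ± 0.13 (adjusted p = 0.00152), Retreg1, a receptor for autophagy of the endoplasmic reticulum, by 1.14 ± 0.11 (adjusted p = 0.000713), and Foxo3 by 1.03 ± 0.14 (adjusted p = 0.00496). The mitochondrial carrier genes Slc25a22, Slc25a25, Slc25a47 and Slc25a51 rose by 1.13 ± 0.11, 0.94 ± 0.13, 1.01 ± 0.13 and 0.95 ± 0.12 (adjusted p = 0.000703, 0.0058, 0.0038 and 0.00331). Mid1ip1, an activator of fatty acid synthesis, fell 2.63-fold (adjusted p = 0.00175) and the insulin receptor substrate gene Irs1 by 0.88 ± 0.15 on the log2 scale (adjusted p = 0.0163). The tight junction genes Cldn1 and Cldn3 fell by 0.82 ± 0.12 and 0.81 ± 0.13 (adjusted p = 0.00788 and 0.00907).

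Of 22 heat shock proteins and chaperones, 4 rose and 18 had values above 0 after stress. If only 1 of the experiments carried the pattern, the list median in the other would lie near 0. It was 0.75 in experiment 1, with 20 of 22 members higher, and 0.27 in experiment 2, with 17 of 22 higher. Both medians lay above the bound set in advance, but that of experiment 2 by no more than the spread of a median over its members. The question was therefore left undecided. A candidate explanation is a warmer liver in the stressed mice, for which cold-inducible transcripts should be lower. Of the 2 such genes chosen in advance, Cirbp was measured and fell (log2 fold change -1.06 ± 0.20, adjusted p = 0.0235), but not past the threshold with no filter (0.112) or no trend (0.0572), and Rbm3 was not measured, so the result is consistent with warming but rests on a single gene whose call depended on these settings, and other effects of the stress session stay open.

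Cdkn1a and Trp53inp1, both known as p53 targets, rose after stress. Had p53 activation been the cause, its direct targets Mdm2 and Ccng1 should have risen as well. Their log2 fold changes were 0.09 ± 0.16 and -0.14 ± 0.13 (adjusted p = 0.892 and 0.754), and the higher of their upper 95% limits was 0.45. Neither of these 2 targets was called, but both were picked after the values were seen, so they cannot decide whether p53 was activated. Of the 33 measured genes of apoptosis and p53 targets, 8 rose, Cdkn1a and Trp53inp1 among them, 1 fell and 24 did not pass. So p53 activation as such is not excluded. Induction by glucocorticoids, which the list of such genes holds for Cdkn1a, may account for that rise but was not tested separately, and no technical explanation was tested.

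Lgr5, Rnf43, Tbx3, Fzd7 and Fzd8, Wnt receptor and target genes that were put together because they fell and were not tested as a set, had log2 fold changes of -1.21 ± 0.19, -1.14 ± 0.23, -0.89 ± 0.19, -1.64 ± 0.19 and -1.21 ± 0.22 (adjusted p = 0.00961, 0.0304, 0.0368, 0.00168 and 0.02). The calls of Rnf43 without stress pool 1 (-1.02, adjusted p = 0.0564) or control pool 2 (-0.94, 0.0674) and of Tbx3 without stress pool 2 (-0.70, 0.172) or after quantile normalization (-0.83, 0.0552) were lost, as were those of Lgr5, Rnf43, Tbx3 and Fzd8 with no filter and of Tbx3 and Fzd8 with no trend, and over the pseudocounts tried Lgr5 ran from -1.42 to -0.76 and Rnf43 from -1.42 to -0.66. Pieces of liver with less tissue around the central veins would lower pericentral genes, but the median over Cyp2e1, Cyp1a2, Oat, Glul, Slc1a2 and Rhbg was -0.07, which argues against it. Lower Wnt signalling should lower further targets. The median over 6 of them (Axin2, Notum, Lect2, Glul, Slc1a2 and Rhbg) was -0.09, with 0 lower past the threshold. These 6 were picked after the targets that fell had been set apart, so the result cannot decide whether Wnt signalling fell. Both tests used Glul, Slc1a2 and Rhbg, so they are not independent. Stable transcripts could lag behind a signal that fell within the session, so a change in short-lived transcripts of this group stays open.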
